A study of Homo sapiens with 6 samples.

How the data were processed

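RNA was sequenced from 6 samples of PC3 cells grown in RPMI-1640 with fetal bovine serum, 3 treated with RSM3 and 3 Control. Per the labels' protocols, poly(A) RNA was made into strand-marked libraries by the dUTP method and sequenced as paired reads on a NovaSeq instrument. The submitters' processing notes name fastp, STAR (2.7.1a), featureCounts, DESeq2 and the human build hg38, with no order or role. The annotation release, the strand setting and the treatment of multiply mapped reads are not given in the sources used here. Counts split between near-identical genes, overlapping genes or antisense partners are therefore uncertain.

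The authors deposited 1 table of whole-number read counts for 60545 genes, with 1 column per sample, and no normalisation had been applied to these deposited counts. Column names matched sample titles one to one, and no column belonged to another sample. Totals per library ran from 14091359 to 18594251 counts. The groups came from the labels, and the replicate numbers from the sample titles. Pairs of libraries of 1 group differed by more than sampling noise, with a chi-square per degree of freedom of 3.33 (RSM3 replicates 2 and 3) to 20.2 (RSM3 replicates 1 and 2), so all 6 were kept as separate samples.

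Genes were filtered with filterByExpr at its default minimum count of 10, which left 15773, of which 12911 were protein coding. RSM3 was compared with Control by the quasi-likelihood F-test of edgeR (4.0.16, in R 4.3.3), with TMM factors, robust dispersion estimates and no covariate. The TMM factors were 1.02 in each Control library and 0.944, 1.00 and 0.996 in RSM3 replicates 1, 2 and 3. P values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. The common biological coefficient of variation was 10.3%. Standard errors of log2 fold changes were derived from the F statistic, and CPM values in the text are TMM-normalised group means ± SD. Summed CPM of marker genes and single-library CPM of TPM1 use the library total alone.

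The gene lists, 45 in all with 898 genes, covered pathways, complexes and markers of other cell types. The 40 lists with at least 5 measured members were tested with camera in limma (3.58.1) on voom values, at the preset correlation of 0.01 and again with the correlation estimated for each list. Members were counted over all genes and with p values adjusted over the list alone. The lists, the test, the rule for named genes and most alternatives were fixed before the data were examined. That rule took the 10 largest rises and 10 largest falls among called protein-coding genes with a mean of at least 5 CPM in the higher group and no overlap between groups, the 5 genes with the smallest p, and for each list described up to 4 members with the smallest adjusted p (2 by expression where none passed). Other genes named in the text were chosen after their values had been seen, and are members of a list, genes left over in a small count, genes tied to a technical observation or, under other observations, genes outside the lists picked by no fixed rule.

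Coordinates, exonic length and GC content came from GENCODE 29 on GRCh38, which covered 99% of the tested genes. The GC and length correction fitted loess curves (span 0.5, degree 2) to each library's log2 deviation from the mean of the 6 libraries. The first curve was on GC content, and the next, on log2 length, was fitted to what remained. Their sum was entered as an offset. Library totals, genes detected and shares of counts were compared with two-sided exact permutation tests, which cannot give a p below 0.1 for 3 samples against 3.

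The scripts were tested on simulated counts with the mean gene shares of the Control libraries and the dispersions and totals of all 6 libraries. The filter left 15981 simulated genes. Of 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 3-fold, edgeR recovered 58.2%, 88.1% and 97.0%. Of its calls, 6.28% were false. In other simulated counts (15976 genes), 10.3% of the calls of DESeq2 and 7.07% of those of limma voom were false. A further simulation (15954 genes) added a trend with GC content to RSM3 replicate 1. The size of this trend was chosen and not fitted to the one measured in that library. The shares recovered by edgeR were then 40.3%, 70.1% and 93.9%, with 0.662% of its calls false. After the correction they were 59.7%, 85.1% and 95.5%, with 6.38% of calls false. The simulated dispersions came from a fit that held the measured trend, so these shares do not measure the loss in these data. In the first simulation, camera called the 1 list given a shift and 0 of 39 unchanged lists. Those simulated genes were independent, so this says nothing of correlated lists.

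The alternatives fixed beforehand were DESeq2 size factors, library size alone, no filter, a filter of 1 CPM in at least 3 libraries, DESeq2 (1.42.0), limma voom, the replicate number as a block, an estimated correlation and leaving out each library in turn. Those added after the data had been seen were the GC and length correction, a term for Control replicates 1 and 2, both together, the correction without RSM3 replicate 1, protein-coding genes alone and thinning to the lowest total. With group in the model, the term sets both RSM3 and Control replicates 1 and 2 against Control replicate 3 alone. XIST and Y-linked genes were left out of the named genes, and a few other genes that the rule took are not reported here.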

Results

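Gene expression was measured by RNA sequencing in PC3 cells, a human prostate cancer line derived from a bone metastasis, which lack functional p53 and androgen receptor. The 6 libraries form 2 groups, 3 from cells treated with RSM3, described in the labels as a peptide, and 3 from Control cells. The labels give neither the dose nor the duration of the treatment. Nor do they say whether the replicates were separate cultures, so every p-value below measures only the spread between these samples, which may be technical. The Control libraries held 16637873, 17264089 and 18594251 counts on genes, and the RSM3 libraries 14091359, 16036658 and 15607019. RSM3 libraries had fewer detected genes, 23462 ± 443 against 25200 ± 70.3 in Control (SD, n = 3 per group; two-sided exact permutation test, p = 0.1, the smallest p this design allows). Thinning all libraries to the lowest total left 23260 ± 268 against 24567 ± 112 genes (exact p = 0.1).

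The comparison asked which transcripts change in PC3 cells exposed to RSM3. CXCL8, which encodes the neutrophil-attracting chemokine interleukin-8, rose from 6.56 ± 1.64 to 37.5 ± 7.29 counts per 1000000 (CPM, mean ± SD, n = 3), a log2 fold change of 2.51 ± 0.19 (SE; edgeR adjusted p = 1.14e-05). BIRC3, an inhibitor of apoptosis, rose from 10.2 ± 0.407 to 51.6 ± 9.59 CPM (log2 fold change 2.34 ± 0.14, adjusted p = 3.11e-06). The chemokine genes CXCL1 and CXCL6, the NF-κB subunit gene RELB, the NF-κB inhibitor gene NFKBIA and the matricellular gene CCN2 each rose at least 2-fold. Among called protein-coding genes with at least 5 CPM in the higher group, the largest fall was that of MAP2K6, a kinase that activates p38, from 45.8 ± 1.95 to 18.5 ± 4.07 CPM (log2 fold change −1.30 ± 0.14, adjusted p = 0.000167).

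Of 15773 genes tested, 488 rose and 174 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 2804 had an unadjusted p under 0.05. The change was at least 2-fold for 55 of the genes that rose and 22 of those that fell. For all 662 genes the values of the 3 RSM3 libraries lay outside those of the 3 Control libraries, as they did for 23.9% of the genes tested, against 10% by chance. Of the 662, 634 were protein coding and 18 were long non-coding RNAs. Rises made up 73.7% of the calls with TMM scaling and 54.8% (308 rises and 254 falls) with library size alone, which moved the median log2 fold change of all genes from −0.0048 to −0.06. The count depended most on RSM3 replicate 1: without it, 2393 genes passed, whereas without Control replicates 1, 2 or 3 or RSM3 replicates 2 or 3 there were 223, 214, 403, 341 and 291.

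RSM3 replicate 1 differed from the other libraries in its relation to base composition. Across genes, the Spearman correlation between a library's log2 deviation from the 6-library mean and the GC content of the transcript was 0.403 in that library, −0.311 and −0.283 in the other RSM3 libraries, and 0.136, 0.157 and −0.197 in Control replicates 1, 2 and 3 (genes are not independent replicates). Removing each library's trend with GC content and length, a step chosen after the data had been seen, gave 865 rises and 517 falls, including 649 of the 662 genes. Control replicates 1 and 2 also stood apart: processed pseudogenes took 0.164% and 0.166% of their counts, against 0.120% to 0.129% in the other 4 libraries, and TPM1, a tropomyosin gene, stood at 103 and 111 CPM against 29.4 to 31.8. With a term for these 2 libraries, likewise added later, 100 genes rose and 18 fell, 89 of them among the 662. That fit compares RSM3 with Control replicate 3 alone, which is assumed to vary like the other libraries.

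**Figure D1:**
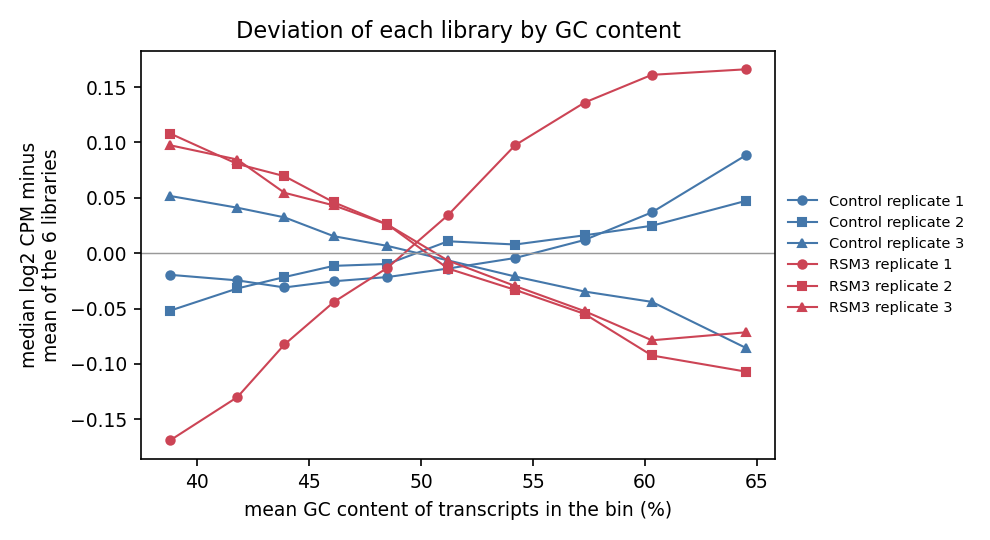
Median deviation of each library from the mean of the 6 libraries (log2 CPM, vertical axis) in 10 bins of genes ordered by the GC content of their transcripts (%, horizontal axis), with 1 line per library. RSM3 replicate 1 rose from −0.17 in the lowest bin to 0.17 in the highest, while RSM3 replicates 2 and 3 ran from 0.11 and 0.10 down to −0.11 and −0.07.

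Genes of a list of NF-κB genes and inflammatory cytokines rose together. NF-κB is a transcription factor family that drives inflammatory gene expression, and its activity was not measured here. Of 22 measured members of the list, 15 rose and none fell, with 16 rises when adjusted over the list alone, and the median log2 fold change was 1.09. Beyond CXCL8 and BIRC3, CXCL1 (chromosome 4, 73869393 to 73871242, GRCh38) rose from 5.60 ± 0.730 to 20.6 ± 0.855 CPM, with a log2 fold change of 1.88 ± 0.14 (edgeR adjusted p = 1.14e-05). LIF, a cytokine of the interleukin-6 family (chromosome 22, 30240447 to 30246851), was already abundant in Control at 214 ± 8.36 CPM and reached 501 ± 59.2 CPM in RSM3. RELB rose from 6.13 ± 1.26 to 25.8 ± 4.91 CPM, and NFKBIA from 55.8 ± 5.27 to 145 ± 25.3 CPM. The list stood above all other genes (limma camera, adjusted p = 1.84e-23), and its adjusted p = 0.110 with an estimated correlation between members. Transcripts of leukocyte markers summed to 3.65 CPM in Control and 1.72 CPM in RSM3, and none of the 14 reached the expression filter.

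**Figure D2:**
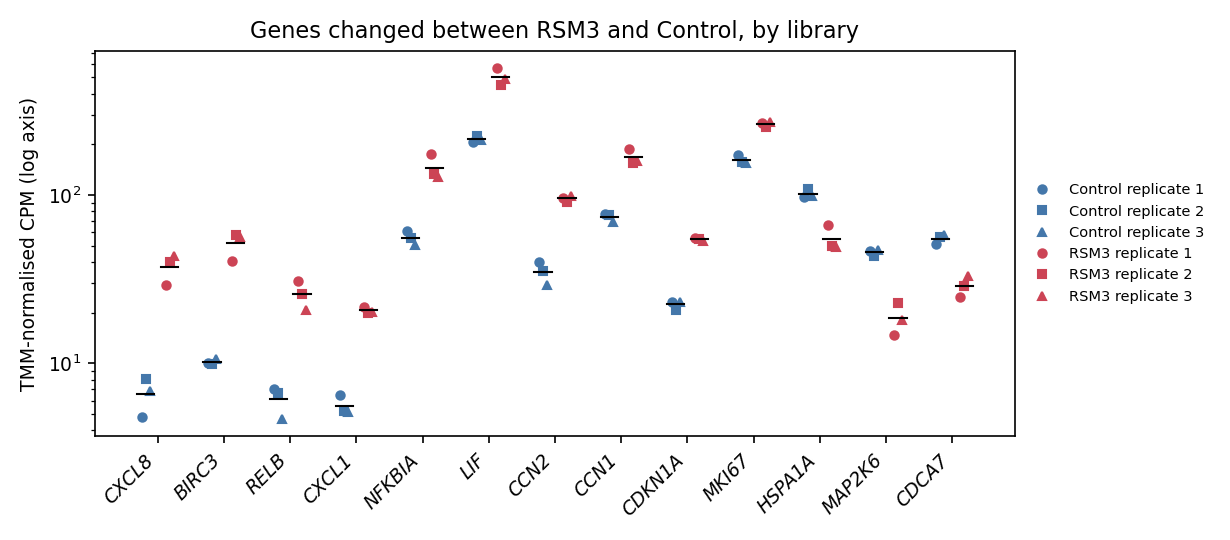
TMM-normalised CPM (logarithmic vertical axis) of 13 genes in each of the 3 Control (blue) and 3 RSM3 (red) libraries, with symbols for the replicate and a black line at the mean of each group. All 3 RSM3 libraries lay above all 3 Control libraries for the 10 genes from CXCL8 to MKI67, and below them for HSPA1A, MAP2K6 and CDCA7.

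Regulators of apoptosis on both sides were among the genes that rose. Of 11 pro-survival genes, BIRC3, BIRC2, BIRC5 and BCL2A1 rose and none fell, with 5 rises when adjusted over the list alone (median log2 fold change 0.16, mean 0.46, camera adjusted p = 5.40e-05, and adjusted p = 0.208 with an estimated correlation). Of the 11, 2 also belong to other lists, BIRC3 to the NF-κB list, so this rise is not separate from those lists. BIRC2, which neighbours BIRC3 on chromosome 11 (102347211 to 102378670 and 102317450 to 102339403), rose from 83.6 ± 4.32 to 178 ± 20.5 CPM (edgeR adjusted p = 3.46e-05). Of 20 pro-death genes, TNFRSF10B, which encodes a TRAIL death receptor, and BMF, a BH3-only gene, rose and none fell, with 3 rises when adjusted over the list alone. The pro-death list had a camera adjusted p = 0.0343, adjusted p = 0.208 with an estimated correlation. It lost its call in 7 of 14 other settings: without Control replicate 1, without RSM3 replicate 2, with the stricter filter, with protein-coding genes alone, with the GC and length correction, with the term for Control replicates 1 and 2 and with both of these. Its median in the last was 0.01. BCL2A1 (log2 fold change 0.73) was not called when any library other than RSM3 replicate 1 was left out.

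The immediate early genes, induced within minutes of a stimulus, rose in 14 of 25 measured members, with 19 rises when adjusted over the list alone and none falling. JUN rose from 81.5 ± 12.9 to 147 ± 16.0 CPM, JUNB from 43.5 ± 8.36 to 89.7 ± 16.3 CPM, ATF3 from 8.41 ± 1.12 to 17.5 ± 2.72 CPM and NR4A1 from 8.95 ± 0.635 to 19.7 ± 4.17 CPM, with edgeR adjusted p values of 0.00139, 0.00159, 0.00187 and 0.00143. The median of the list was 0.56 (camera adjusted p = 2.72e-16, and adjusted p = 0.139 with an estimated correlation). JUN and JUNB were past the threshold with all libraries but not without RSM3 replicate 1, where their log2 fold changes were 0.79 and 0.91 (adjusted p = 0.065 and 0.068).

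Targets of YAP and TAZ, the transcriptional effectors of the Hippo pathway, rose in 12 of 20 members, with 14 rises when adjusted over the list alone and no falls. CCN2 (chromosome 6, 131948176 to 131951373) rose from 34.9 ± 5.45 to 95.5 ± 3.69 CPM (log2 fold change 1.45 ± 0.11, edgeR adjusted p = 1.28e-05), CCN1 from 74.2 ± 4.55 to 168 ± 18.3 CPM and ANKRD1 from 1.95 ± 0.547 to 7.83 ± 0.432 CPM. The growth factor gene TGFB2 rose from 12.3 ± 0.348 to 21.5 ± 1.62 CPM. The list's median was 0.37 (camera adjusted p = 1.38e-12, and adjusted p = 0.139 with an estimated correlation). Targets of TGF-β signalling also rose in 5 of 17 members, ID3, JUNB, SKIL and BHLHE40 among them, and 12 did not pass, with 5 rises when adjusted over the list alone (median 0.18, camera adjusted p = 3.77e-05, and adjusted p = 0.139 with an estimated correlation). Of the 18 genes on this list, 4 also belong to other lists, JUNB to the immediate early list and BHLHE40 to the hypoxia list. The call of JUNB was lost without RSM3 replicate 1, that of SKIL without Control replicate 1, Control replicate 2 or RSM3 replicate 3, and that of BHLHE40 without any library but RSM3 replicate 1. The median of the TGF-β list was 0.30 without RSM3 replicate 3.

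Mitotic genes rose in 12 of 23 measured members, 16 when adjusted over the list alone, against 1 fall over the list alone and none over all genes. MKI67, the proliferation marker Ki-67, rose from 162 ± 9.84 to 265 ± 9.45 CPM (log2 fold change 0.71 ± 0.08, edgeR adjusted p = 0.000234). The kinesins KIF23 and KIF20A and the ubiquitin-conjugating enzyme gene UBE2C rose by 0.87, 0.66 and 0.58 on the log2 scale. The list's median was 0.48 (camera adjusted p = 1.23e-14, and adjusted p = 0.139 with an estimated correlation). Genes of DNA replication went both ways: RRM2, TYMS and RRM1, which supply nucleotides, rose, E2F2, UHRF1 and MCM10 fell and 20 of 26 did not pass (median −0.09, camera adjusted p = 0.146), with 4 rises and 5 falls when adjusted over the list alone. The replication median ran from −0.13 without Control replicate 2 to −0.03 without RSM3 replicate 1, and 2 of 14 other settings called the list lower. RRM1 was not called without any library but RSM3 replicate 1, nor MCM10 without Control replicate 2. The mean difference between the medians of the mitotic and replication lists was 0.23 ± 0.16 in RSM3 libraries and −0.28 ± 0.04 in Control libraries (log2 deviation, SD, n = 3; exact permutation test, p = 0.1, the smallest possible).

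CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 22.5 ± 1.39 to 54.6 ± 0.994 CPM (chromosome 6, 36676460 to 36687339; log2 fold change 1.28 ± 0.09, edgeR adjusted p = 1.14e-05). Among 22 targets of p53, which PC3 cells lack, CDKN1A and TNFRSF10B were the genes that rose and none fell, with 6 rises and 2 falls when adjusted over the list alone (median 0.15, camera adjusted p = 0.00618, and adjusted p = 0.139 with an estimated correlation). The median was 0.09 without RSM3 replicate 2 and 0.23 without RSM3 replicate 3. The remaining genes with the smallest p values were SAMD4A, an RNA-binding repressor of translation, at 109 ± 2.84 CPM in Control and 259 ± 10.3 CPM in RSM3, and DENND3, an exchange factor for RAB12, at 145 ± 2.97 and 315 ± 27.8 CPM. CLDN1, a tight junction gene, rose from 12.1 ± 1.11 to 33.0 ± 2.15 CPM, and VNN1, a pantetheinase gene, from 1.74 ± 0.542 to 5.25 ± 0.534 CPM.

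Stress responses moved in different directions. Cytosolic heat shock genes were lower: HSPA8 fell from 3133 ± 107 to 2086 ± 132 CPM and HSPA1A from 102 ± 6.44 to 55.1 ± 9.55 CPM, while 14 of 16 did not pass and 6 fell when adjusted over the list alone (median −0.16, camera adjusted p = 1.56e-05, and adjusted p = 0.139 with an estimated correlation). HSPA1A shares nearly its whole sequence with HSPA1B, which stood at 69.4 ± 5.53 and 55.3 ± 12.3 CPM (adjusted p = 0.208), so the value of each alone is uncertain. Of 22 ATF4 targets of the integrated stress response, ATF3, CHAC1, STC2, PPP1R15A and MTHFD2 rose while PHGDH and PSAT1, which make serine, fell, with 10 rises and 2 falls when adjusted over the list alone (camera adjusted p = 0.00135, and adjusted p = 0.324 with an estimated correlation). Of these 22, 6 also belong to other lists, ATF3 to the immediate early list. The median of the ATF4 list, 0.22, was 0.11 without RSM3 replicate 1 (camera adjusted p = 0.0488) and 0.33 without RSM3 replicate 3. TXNRD1, the cytosolic thioredoxin reductase, rose from 1679 ± 153 to 2747 ± 102 CPM, one of 3 rises against 1 fall among 21 NRF2 targets (3 and 1 adjusted over the list alone, camera adjusted p = 0.0521, called higher in 3 of 14 other settings). Among 20 ER chaperone and ERAD genes PDIA4 fell and the others did not pass (1 rise and 2 falls adjusted over the list alone; the list was not called, but was called lower in 2 of 14 other settings). PHGDH and PSAT1 lost their calls when any library but RSM3 replicate 1 was left out, CHAC1 without Control replicate 2 or 3, and PDIA4 without Control replicate 1 or 2 or RSM3 replicate 2 or 3.

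Metabolic and housekeeping groups shifted by small amounts. Of 31 proteasome genes PSMC3, PSMB1 and PSMB5 rose, with 9 rises when adjusted over the list alone, and the median was 0.18 (camera adjusted p = 2.00e-08, and adjusted p = 0.139 with an estimated correlation). Of 18 glycolysis genes PFKFB3, PGK1 and TPI1 rose, with 10 rises when adjusted over the list alone (median 0.23, camera adjusted p = 8.75e-06, and adjusted p = 0.275 with an estimated correlation). Without RSM3 replicate 1 the glycolysis median was 0.15. Hypoxia targets rose in 4 of 18 (BNIP3L, BHLHE40, MXI1 and ADM; 6 adjusted over the list alone), nuclear oxidative phosphorylation genes in 4 of 40 and cytosolic ribosomal protein genes in 3 of 48 (4 each adjusted over the list alone), with camera adjusted p values of 8.90e-05, 2.36e-05 and 5.91e-08 that became adjusted p = 0.139, 0.208 and 0.211 with an estimated correlation. Regrouping the 6 libraries with Control and RSM3 mixed gave the ribosomal list a smaller unadjusted camera p (2.529e-09) than the real grouping (8.865e-09). The proteasome, glycolysis and hypoxia genes named here each lost their calls in at least 3 of the 6 fits that left out 1 library, among them those without Control replicate 1 and without Control replicate 2, and kept them without RSM3 replicate 1.

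No interferon-stimulated gene passed among 29 measured. Their median was 0.20 (camera adjusted p = 0.0184, and adjusted p = 0.618 with an estimated correlation), and OAS3, an antiviral oligoadenylate synthetase gene, stood at 574 ± 112 CPM in Control and 688 ± 198 CPM in RSM3 (edgeR adjusted p = 0.534). The list was highest in RSM3 replicate 1 and lowest in Control replicate 1, and its call ended when either was left out, with medians of −0.02 and 0.02. The median was 0.34 without Control replicate 3 and 0.33 without RSM3 replicate 3. None of 13 mitochondrially encoded mRNAs passed, and their share of all counts was 3.29 ± 0.257% in Control and 3.46 ± 0.622% in RSM3 (exact permutation test, p = 0.8). Their list was not called (median 0.11, camera adjusted p = 0.0677), but was called higher in 5 other settings and lower in 1. Without RSM3 replicate 1 its median was −0.05, and without each of the other libraries it was 0.07 to 0.21.

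Besides MAP2K6, the genes with the largest falls at that level of expression were MYB, FRK, PCDH18, RP1, TNS2, NFIA, CDCA7, SHC3 and SHANK2. TNS2, a focal adhesion protein gene (chromosome 12, 53046969 to 53064372), fell from 48.4 ± 2.85 to 23.6 ± 7.44 CPM, and CDCA7, a zinc finger gene regulated by MYC and E2F, from 54.9 ± 3.55 to 28.9 ± 3.95 CPM (edgeR adjusted p = 0.00319 and 0.00052). PCDH18, a protocadherin, fell from 10.3 ± 0.113 to 4.61 ± 1.07 CPM and SHANK2, a scaffold protein, from 18.1 ± 0.247 to 9.51 ± 0.983 CPM. Of 12 fatty acid synthesis genes ACSL3 and MID1IP1 fell and none rose, with 4 falls when adjusted over the list alone (camera adjusted p = 0.0109, and adjusted p = 0.139 with an estimated correlation). The list's median of −0.12 was −0.03 without Control replicate 1 and −0.18 without Control replicate 3. Its call was lost without RSM3 replicate 2, and those of ACSL3 and MID1IP1 without any library but RSM3 replicate 1. MYB, FRK, NFIA and SHC3, at or below 8.16 CPM in Control, each lost their calls in 3 or more of the fits that left out 1 library, Control replicate 2 and RSM3 replicate 3 among them.

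**Figure D3:**
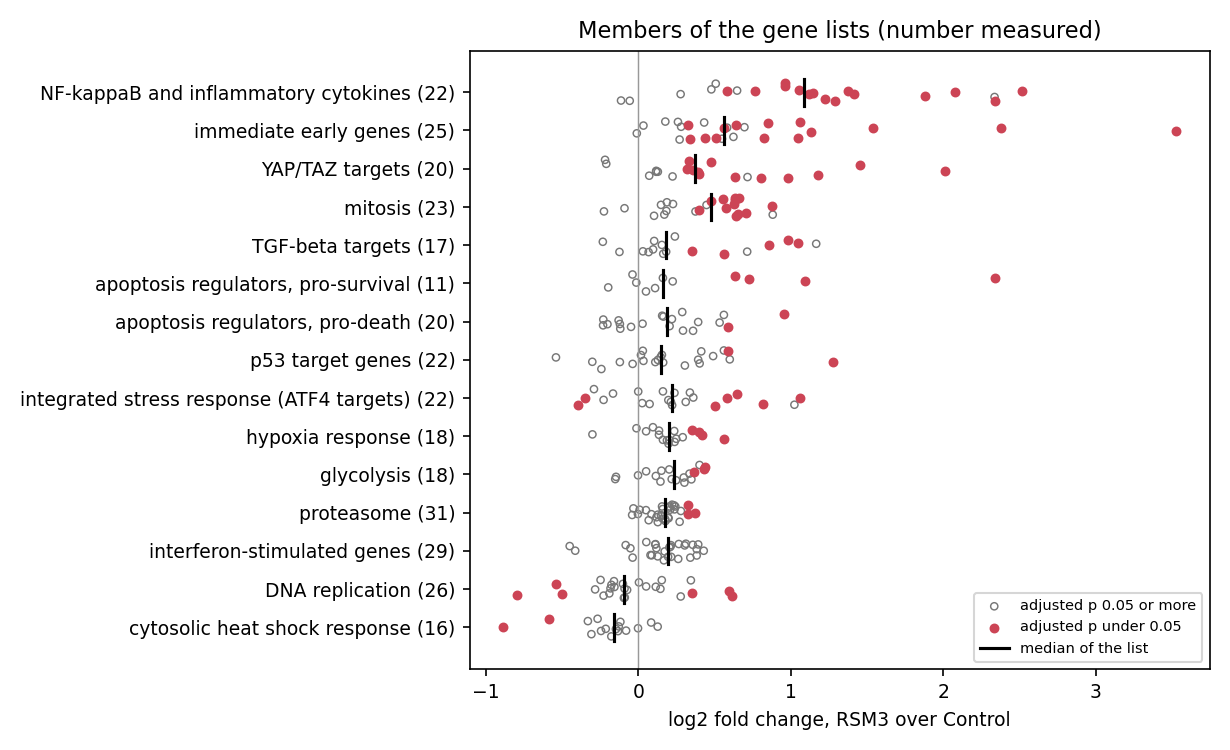
Log2 fold changes of RSM3 over Control (horizontal axis) for the measured members of 15 gene lists (vertical axis, number measured in brackets); filled points had an edgeR adjusted p under 0.05 and black lines mark medians. The medians ran from 1.09 for the NF-κB list to −0.16 for the heat shock list. EGR1 and FOS, the immediate early genes farthest to the right, stood at 0.162 and 0.485 CPM in Control, so their positions depend on the prior count.

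Of 40 lists with at least 5 measured members, 21 were higher and 2 lower in RSM3 (camera, adjusted p under 0.05). With an estimated correlation no list passed, at an unadjusted p of 0.00275 for the NF-κB list. The fry test of limma, also planned, asks whether the members of a list move together, without comparing them with other genes. Over the 23 called lists its unadjusted p ran from 6.73e-05 for NF-κB to 0.553 for the interferon-stimulated genes. Cholesterol synthesis, tubulins and actin cytoskeleton, FOXO targets, lysosome, autophagy, and MYC with growth-associated genes were the called lists not described above, with 2 of 25, 4 of 25, 3 of 18, 1 of 24, 2 of 23 and 3 of 18 members higher and none lower over all genes, and 5, 8, 4, 1, 2 and 5 higher and none lower when adjusted over the list alone. MYC itself was among the 3 higher members of the last list. In the fits that left out 1 library, calls were lost without Control replicate 3 for tubulins and actin, Control replicate 3 or RSM3 replicate 1 for FOXO, RSM3 replicate 1 for lysosome, Control replicate 1 or RSM3 replicate 1 for MYC, and these 2, Control replicate 3 or RSM3 replicate 2 for autophagy. With the replicate number as a block, the autophagy list also lost its call, as did the single genes MXI1, ADM, PSAT1 and LAMB1. For the MYC list the median of 0.03 turned negative, −0.03, with library size alone as the scaling. Lists of epithelial, mesenchymal, extracellular matrix, Wnt and ERK output genes were not called. Of 14 other settings, however, 9 called the epithelial list higher and 5 the mesenchymal list, and the other 3 lists were called in none. The epithelial median of 0.14 was 0.01 without RSM3 replicate 1 and 0.23 without Control replicate 1. Within them CLDN1, CLDN4, PLAU (the urokinase gene), LAMB3, THBS1, DKK1, MYC, DUSP5, HBEGF, DUSP6 and IER3 rose, and LAMA5, LAMB1 and AREG fell. Of these, CLDN1, PLAU, DUSP5 and HBEGF were called in all 18 alternatives run, whereas CLDN4, MYC, DUSP6, IER3 and LAMB1 lost their calls when any library but RSM3 replicate 1 was left out, and LAMA5, AREG and THBS1 in fits that included the one without Control replicate 1. Of 8 measured androgen receptor and luminal prostate genes, TMPRSS2 rose from 49.8 ± 1.75 to 74.7 ± 2.20 CPM, STEAP2 fell from 26.4 ± 3.30 to 15.6 ± 2.19 CPM and HOXB13 fell from 499 ± 12.4 to 370 ± 23.1 CPM. There were 2 rises and 3 falls when adjusted over the list alone. That list was not called (median 0.19, camera adjusted p = 0.875), and its median was 0.10 without Control replicate 1 and 0.09 without RSM3 replicate 1, where camera's direction was lower. HOXB13 lost its call without Control replicate 1 or 2 or RSM3 replicate 3. Fibroblast and endothelial markers had 3 and 4 measured members, of which PDGFRA and KDR fell. The call of PDGFRA was lost without any library but RSM3 replicate 1, and that of KDR without Control replicate 1 or 2. Neuroendocrine genes and markers of red cells and hepatocytes had 4 and 2, none of which passed.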

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

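The cause of the differences below was not tested. The main counts were 488 rises, 174 falls and 77 changes of at least 2-fold. Rises numbered 308 with library size alone, and falls 392 without a filter, where 171 genes reached 2-fold, and 268 with DESeq2. Leaving out 1 library at a time gave 177 to 1447 rises, 37 to 946 falls and 50 to 142 changes of 2-fold, highest without RSM3 replicate 1. In alternatives chosen after seeing the data, the GC and length correction gave 865 rises and 517 falls, a term for Control replicates 1 and 2, which leaves Control replicate 3 alone against RSM3, gave 100 and 18, and the correction without RSM3 replicate 1 gave 1204 and 852, with 130 of at least 2-fold.

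Lists called were 21 higher and 2 lower, and 0 and 0 with an estimated correlation. Lower lists numbered 1 with the term, 6 with the correction without RSM3 replicate 1, and 1 to 3 when leaving out 1 library, against 17 to 25 higher. Of the 23 lists, 15 kept their call in all 14 other settings in which camera was run at the preset correlation. Camera was not run with library size alone, without a filter, or with DESeq2 or limma voom. The interferon list lost its call without Control replicate 1, where its median was 0.018. The median had a range from −0.0186 (without RSM3 replicate 1) to 0.34 (without Control replicate 3) over the fits without 1 library. Its median was −0.0468 with the term, −0.0655 with term and correction, and −0.0434 with the correction without RSM3 replicate 1. That last setting put mitochondrially encoded mRNAs at −0.18 (camera adjusted p = 0.000414), whereas they were called higher with the replicate block, without Control replicate 1, RSM3 replicate 2 or RSM3 replicate 3, and with the term (medians 0.10, 0.18, 0.21, 0.16 and 0.20).

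Replicate numbers did not pair the samples: correlations of deviations between same-numbered libraries were 0.03, −0.025 and 0.044. With the number as a block, 467 genes rose and 186 fell, and the best partners of Control replicates 1, 2 and 3 were RSM3 replicates 1, 1 and 2. Of 132 genes that passed and whose values were followed, 32 kept their call in all 18 alternatives and none changed direction past the threshold. The difference in genes detected moved from −1738 to −1308 after thinning. In simulation 58.2% of 1.5-fold changes were recovered, and 40.3% with a GC trend of a chosen size, not the measured one, in RSM3 replicate 1.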

Other observations

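The genes of this and the next paragraph, the corrections for GC content and for Control replicates 1 and 2, and the test on olfactory receptor genes were chosen after the results had been seen. The genes named in these 2 paragraphs lie outside the fixed lists, and no enrichment was tested for them. CD274 and PDCD1LG2, neighbours on chromosome 9 that encode the ligands of the PD-1 receptor, rose from 8.95 ± 0.685 to 16.3 ± 0.796 CPM and from 3.27 ± 0.502 to 6.57 ± 0.830 CPM (mean ± SD, n = 3; edgeR adjusted p = 0.00214 and 0.0142). CD83, a surface marker of mature dendritic cells, rose from 14.6 ± 1.59 to 34.3 ± 3.93 CPM, and IL23A, which encodes a subunit of interleukin-23, from 1.04 ± 0.266 to 3.19 ± 0.674 CPM. IRAK2, a kinase of Toll-like and interleukin-1 receptor signalling, rose from 25.4 ± 1.09 to 51.8 ± 6.23 CPM, TNIP1, an inhibitor of NF-κB signalling, from 112 ± 5.50 to 190 ± 39.1 CPM, and IRF1 from 17.7 ± 0.193 to 28.5 ± 4.72 CPM. CD83 and IRAK2 were called in all 18 alternatives run. PDCD1LG2 lost its call without Control replicate 1 or RSM3 replicate 3, IL23A without Control replicate 2 or RSM3 replicate 2, and IRF1 without Control replicate 1 or 2.

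FOXA1, a pioneer factor of the prostate lineage, fell from 141 ± 21.6 to 93.0 ± 4.76 CPM (log2 fold change −0.60 ± 0.11, edgeR adjusted p = 0.0068) and HOXA10 fell by 0.66 on the log2 scale. TET1, a DNA demethylase gene, fell from 7.90 ± 0.370 to 4.67 ± 0.916 CPM. FOXA1 was not called without Control replicate 1 or 2, HOXA10 without any Control replicate or RSM3 replicate 2, and TET1 without any library but RSM3 replicate 1.

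The rise of the NF-κB list (15 of 22 members, median log2 fold change 1.09) was set against 3 technical explanations. The tables argue against a trend with GC content and length as the whole cause, since the median was 1.05 after its removal (camera adjusted p = 1.15e-23; the uncorrected list had adjusted p = 0.110 with an estimated correlation). They argue against leukocyte RNA too: the summed CPM of leukocyte markers changed by −1.93 while CXCL8 rose by 30.2 CPM, and PTPRC, CD74 and LYZ were at most 1.74, 0.579 and 0.481 CPM in any library. The difference of Control replicates 1 and 2 stays open: with a term for them the median was 1.25, but this fit sets RSM3 against Control replicate 3 alone, and 1 library cannot decide it. Whether the peptide itself, another component of its preparation such as endotoxin, or a change of medium gave the rise stays open and untested.

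The mitotic list was higher without a rise of the DNA replication list. The tables argue against the GC and length trend as the whole cause, since the mitotic median was 0.44 after its removal, against 0.48 before (camera adjusted p = 1.82e-14 after it; the uncorrected list had adjusted p = 0.139 with an estimated correlation). The difference of Control replicates 1 and 2 stays open, since the median of 0.54 with the term rests on Control replicate 3 alone. A larger share of cells in G2 or mitosis may be the cause and stays open and untested: 12 members rose and 11 did not pass. Among those 11, named after their values were seen, CCNB2, PLK1 and AURKA had log2 fold changes of 0.38, 0.23 and 0.19 (called in 1, 0 and 0 of 18 alternatives), CCNB1 −0.09 (called in 0) and CDC20 −0.23 (called lower in 3).

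Control replicates 1 and 2 carried more counts on processed pseudogenes than the other 4 libraries. Genomic DNA in these libraries is argued against by 381 olfactory receptor genes, most of them rarely transcribed in epithelial cells. They summed to 14.85 and 13.96 CPM in Control replicates 1 and 2 (mean 14.4), and to 14.84 to 18 CPM in each other library. Whether transcription of some of these genes masks a small difference was not tested. Reads shared with expressed parent genes could account for the excess: over Control replicate 3 it was 0.50 (log2, median of 141 pseudogenes) where the parent was at 100 CPM or more and 0.18 (54 pseudogenes) elsewhere, but the difference of 0.31 had a permutation p of 0.0576, so this explanation cannot be told apart from others with this number of genes. No biological explanation was tested, since both libraries belong to the Control group with replicate 3. With a term for the 2 libraries, which with group in the model sets them against Control replicate 3 alone, 10 genes differed, led by TPM1 (log2 1.76, edgeR adjusted p = 0.00129), and a single processed pseudogene of 288 was among them.

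Whether chance regrouping could give as many calls was counted over all 10 splits of the 6 libraries into 3 and 3. The real split gave 662 genes and 77 genes with a change of at least 2-fold, and the highest of the other 9 splits gave 0 and 0. Of gene lists the real split called 23, and the others between 7 and 17, all by camera at the preset correlation. With an estimated correlation the real split called 0 lists. In 1 of 10 splits, the real one, the result was as large for each of the 3 counts, and 10 splits cannot give a share under 0.05. Each other split leaves 2 libraries of 1 group on one side and 1 on the other, so part of the treatment difference remains in it. Any difference between the real groups also widens the spread within each side, which by itself can bring the gene counts to 0. The gene counts therefore cannot tell the treatment from another difference between the groups. How many list calls of the other splits come from single libraries cannot be read from these counts. For 16 of the 23 lists the p of the real split was the smallest of the 10. It was 4.59e-25 for NF-κB against 1.01e-07 at the lowest elsewhere, and 9.22e-16 for mitosis against 2.76e-07. The 23 were picked by their p in the real split, so this share was favoured beforehand and gives no support by itself. Of the 17 lists not called, only the NRF2 list and the polyamine, serine and one-carbon list had their smallest p there. Other splits gave a smaller p for the ATF4, pro-death, ribosomal protein, tubulin and actin, autophagy and lysosome lists. The interferon list reached 6.73e-31 in another split against 0.00919 in the real one.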
